A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

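Poly(A) positions were measured by 3' READS on total RNA from log-phase cultures in rich medium of 1 yeast strain, JZY65, in which the RPB4 coding sequence is deleted. The 2 samples are biological replicates of that strain per the labels, and formed 1 group. Bowtie is named in the submitters' processing notes, and its version and settings, the genome build and the handling of reads that match several places are not given in the sources used here. Each replicate had 1 deposited table, and a further table held both replicates pooled. All 3 tables had 6198 annotated features, 5798 of them ORFs, with coordinates, the downstream neighbour and its distance. ORF coordinates equalled those of assembly R64 for 5787 ORFs. SEE1 is among the others, with a different start. Printed coordinates are the files' own.

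Per the file headers, the authors gave for each feature the reads inside it, the reads in the window from 1 to 400 nt after its end, and the reads at its most used position. These deposited signal values are reads multiplied by 1 factor for the whole library, as the values show, since they are multiples of 0.858 in replicate 1, 0.940 in replicate 2 and 0.897 in the pooled table. The deposited percent values are, per the file headers, shares of a gene's own reads. A further 400 deposited columns give the reads at each position relative to the gene's most used position, which is set to 100. What the factor was chosen for is not given in the sources used here.

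Whole reads were recovered by dividing by the factor. Among positions of genes with at most 2000 reads at their highest position, 99.998% and 99.995% lay within 0.1 of a whole number, and of the window totals 99.1% and 98.8% did. The pooled table equalled the sum of both replicates at all 94421 positions tested (genes with fewer than 1000 reads at their highest position). Every value below comes from these recovered reads. With 1 group, no count test between groups could be run on them, so none of the usual count models applies. The recomputed mean endpoint differed from the deposited one by at most 0.0390 nt.

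Genes used were ORFs with at least 100 window reads in each replicate. The filter was set in advance for values that are counts, and since the deposited values were scaled reads, it was applied to the recovered reads. ORFs alone were used because the tables also hold 400 features of other kinds, a choice made after the tables were opened. Depth was 27449031 and 24960907 window reads over all features, of which ORF windows held 27374989 and 24905308. The 10 most read ORFs took 10.9% and 8.94% of these. Reads inside ORFs made up 2.08% and 2.12% of ORF and window reads. Of the 4939 genes, 1176 have a window that overlaps another feature on the same strand, whose reads cannot be separated from theirs, and 3' ends beyond 400 nt are outside the measurement.

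For each gene and replicate the read-weighted mean position, the most used position (the most upstream one in ties), its share of reads and the effective number of positions were computed, and means are given with the SD over 2 replicates. Sampling noise was estimated from 5 draws of both replicates from the pooled profile. Shares of reads carry Wilson 95% intervals, and a share of 0 carries the limit from 3 counts. Gene lists were compared with all other genes used by the difference of medians against 100000 random lists of the same size, two-sided, with Benjamini-Hochberg adjustment over 16 lists, separately for endpoint and effective number. Lists were also compared with 10000 random lists matched on reads in 10 classes, and ribosomal protein pairs with 10000 random pairings. Neighbour comparisons used 100000 permutations, adjusted over 3 tests. These tests treat genes as the units within 1 strain and say nothing about a difference from another strain.

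Genes were named by a rule fixed before the data were examined. It takes RPB4, then ACT1, CYC1, ADH1, PGK1, TDH3, RNA14, SUA7, CBP1, HIS3 and RPB7. It then takes the 2 shortest and 2 longest members of each list, and the 5 genes with a standard name at each extreme of endpoint, leading share, effective number and difference between replicates. Marker genes of mating type and auxotrophy are members of 2 of the lists. Genes named by read counts, reads inside ORFs, paralog pairs and snoRNAs were picked after their values were seen.

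The list test and the neighbour comparison of medians were tested on simulated data. The neighbour correlations with distance were not. In profiles drawn from the 4939 real genes, 200 of them in 4 lists of 50 were moved downstream by 10, 20, 40 and 80 nt. Measured against each gene's own unshifted profile, the median recovered shifts were 10.0, 19.9, 39.9 and 79.6 nt. This checks the endpoint measure and not the difference between a list and other genes. The permutation test of lists gave p = 0.974, 0.0262, 3e-05 and 1e-05 for these lists, each from 1 draw. Of 200 lists of 50 genes drawn anew for each shift, 15.5%, 52.0%, 99.0% and 100% had p under 0.05 without adjustment. No shift was planted in lists of other sizes. Of 200 random lists of 30 genes, 7.00% had p under 0.05, and of 100 random splits of 1000 genes, 3.00% did. A first version drew the shifted genes from those ending before 200 nt, which lowered their starting medians, and was widened to 300 nt after its result was seen.

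Alternatives were no filter or 1000 reads, positions 1 to 300 or 21 to 400, positions under 1% set to 0, genes without overlapping windows, each replicate alone, the pooled table, and other summaries and correlations. Chosen after seeing the data were all feature types, verified ORFs and thinning to 100 reads. The planned comparison of sequence around the most used position needed a genome sequence, which was not used here, and was not run. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.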

Results

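The series asked which factors shape the choice of polyadenylation sites in budding yeast, using strains that each lack the coding sequence of 1 gene. The samples analysed here came from a strain without the coding sequence of RPB4, a subunit of RNA polymerase II that pairs with Rpb7. Total RNA from log-phase cultures grown in rich medium at 30 °C was sequenced by 3' READS, a method in which each read marks the position where a poly(A) tail was added. There were 2 biological replicates in 1 group. No parental strain was among these samples, so no value below is an effect of the deletion. The comparisons are between the replicates and between genes within the strain, and genes are not independent replicates. The windows of 400 nt after the stop codons of the annotated open reading frames (ORFs) held 27374989 reads in replicate 1 and 24905308 reads in replicate 2. Of the 5798 ORFs, 4939 had at least 100 window reads in both replicates and were used, with a median of 1402 and 1366 reads per gene.

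No read lay inside the deleted RPB4 coding sequence (YJL140W, chromosome X, 150961 to 151626, plus strand) in either replicate. The 0 of 4486 and 0 of 4066 reads allow shares of up to 0.0669% and 0.0738% of the gene's reads. Of 737 other genes with at least as many window reads in both replicates and no same-strand neighbour reaching into them, 13 also had no read inside the ORF in either replicate. The median of the 737 genes was 26 and 29 such reads. The 3' window downstream of RPB4 did hold reads, 4486 and 4066, and it lies outside the deleted part, so it does not check the genotype. The marker and junction of the deletion are not given in the sources used here, so the transcript these reads come from is unknown. Their most used position was 50 nt after the stop codon in both replicates and took 33.2% ± 2.55 (SD, n = 2) of them. Their mean endpoint, the read-weighted mean position of the poly(A) sites, was 78.0 nt ± 1.90 (SD, n = 2). RPB7, the gene of the partner subunit (YDR404C, chromosome IV, 1276654 to 1277169, minus strand), ended at 159.8 nt ± 0.444 (SD, n = 2), with 39.3% ± 2.92 of its reads at 163 nt. PCR reads were counted without molecular identifiers, so limits and intervals here cover counting error only.

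Genes of the mating type and of auxotrophic markers further described the strain. The a-factor genes MFA1 (12488 and 19004 window reads) and MFA2 (15677 and 15107) were read deeply, and the alpha-factor gene MF(ALPHA)1 had 6 and 1 reads. The alpha-factor receptor gene STE2 had 2165 and 3059 reads and the a-factor receptor gene STE3 304 and 189. The alpha-factor gene MF(ALPHA)2 had 0 window reads in both replicates, and 12 and 17 reads inside the ORF. BAR1, an a-specific gene, had 3288 and 4343 window reads. Other such genes did not follow that order. SAG1, of the alpha agglutinin, had 937 and 936 window reads and 98 and 103 inside the ORF, and its window overlaps another feature on the same strand. The a-specific gene STE6 had 174 and 149 window reads and 294 and 332 inside the ORF. AGA2, also a-specific, had 149 and 263 window reads and 140 and 135 inside the ORF. MET17, of methionine synthesis, had 0 reads in both replicates, and LEU2, of leucine synthesis, had 9 in each. URA3 had 159 and 191 window reads and none inside the ORF, and HIS3, of histidine synthesis, had 1783 and 2222 window reads against 0 and 1 inside the ORF. The windows of both overlap another annotated feature on the same strand, so their reads may not be their own.

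The first comparison asked how far the replicates gave the same 3' ends. They shared the most used position in 4139 of 4939 genes (83.8%, Wilson 95% interval 82.7 to 84.8), and in 4325 genes (87.6%) the positions lay within 5 nt. Drawing both replicates from 1 pooled profile per gene, which leaves sampling noise alone, gave 94.1%. The median correlation of the profiles of 1 gene was 0.981, against 0.998 from sampling noise alone and -0.00867 between profiles of different genes. The median chi-square per degree of freedom was 7.63. That measure sets separate cultures, with PCR copies counted as reads, against read sampling alone, so a value above 1 was to be expected. The mean endpoint moved by a median of 2.03 nt between replicates (0.596 nt from sampling noise alone), and lay further from the stop codon in replicate 2 for 2918 genes (59.1%), by a median over all genes of 0.437 nt. Window reads per gene correlated across genes with r = 0.987 on the log2 scale.

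Only 99 genes differed by more than 20 nt in mean endpoint. MCM1, a transcription factor gene, had the largest difference, with 348.2 nt in replicate 1 and 269.4 nt in replicate 2 on 448 and 415 reads. RPL8A, of a large-subunit ribosomal protein, had 131.9 and 182.7 nt on 25600 and 15661 reads. Its most used position was 58 nt in both, and 19.8% and 34.9% of its window reads lay beyond 350 nt. In positions 1 to 300 the mean endpoint over both replicates was 112.7 nt for MCM1 and 74.4 nt for RPL8A. DAN4, of a cell wall mannoprotein (122.3 and 172.5 nt), DHH1, of an RNA helicase (230.7 and 182.3 nt), and CBF1, of a centromere-binding transcription factor (155.2 and 202.9 nt), rested on between 101 and 217 reads per replicate.

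**Figure D1:**
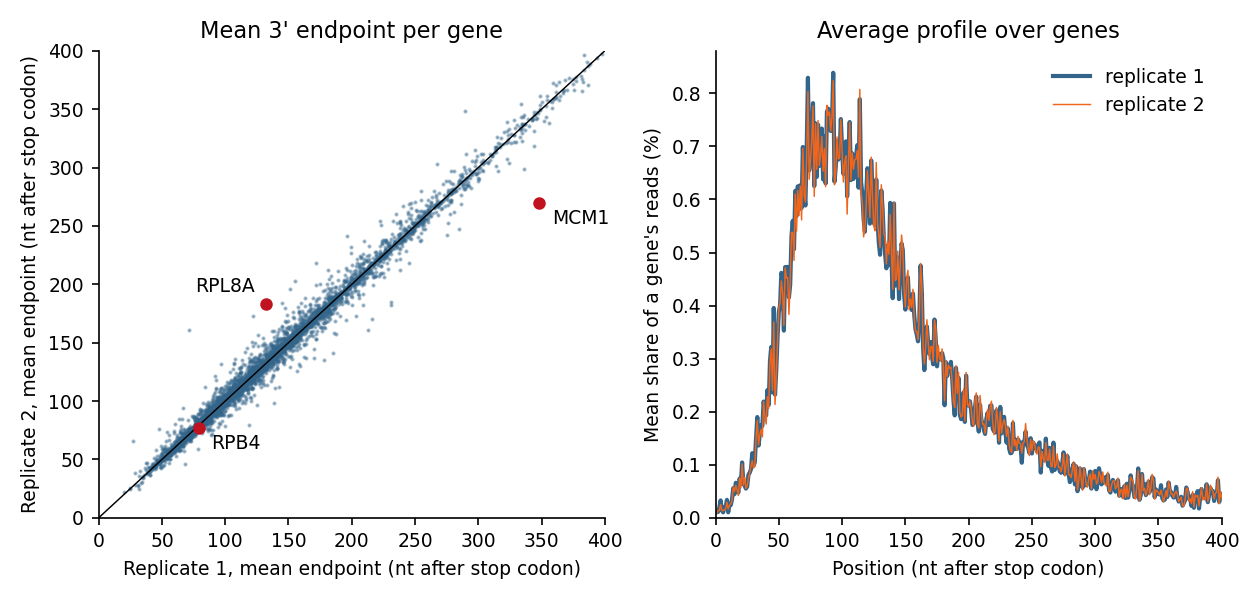
The left panel plots the mean endpoint of each of the 4939 genes (nt after the stop codon) in replicate 1 against replicate 2, with the line of equality and RPB4, MCM1 and RPL8A in red. The right panel plots the mean share of a gene's reads at each position for both replicates (percent), and the curves overlie each other, with 37.8% and 37.3% of the signal within 100 nt.

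The typical yeast 3' end lay 123.0 nt ± 0.940 (SD of the 2 replicate medians, n = 2) after the stop codon in this strain. The middle 90% of genes ran from 60.0 to 268.6 nt. With each gene weighted equally, 66.5% and 66.1% of the signal lay within 150 nt of the stop codon and 5.04% and 5.08% beyond 300 nt. The shortest mean endpoints, among genes with a standard name, were those of ULA1, of the neddylation pathway (21.2 nt ± 1.86, SD, n = 2), HMRA1, of a silent mating-type locus (24.5 nt ± 0.199), KAR1, of the spindle pole body (28.1 nt ± 0.488), SEE1 (29.1 nt ± 3.05) and PEX34, of peroxisomes (29.3 nt ± 2.13). The windows of HMRA1 and KAR1 overlap another feature on the same strand. HMRA1 had 1981 and 1683 window reads. How reads that match several places were placed is not given in the sources used here, so these may not come from the silent locus. The longest were those of RIP1, of respiratory complex III (397.5 nt ± 0.867), HAC1, of the unfolded protein response (394.0 nt ± 0.10), ERC1 (389.9 nt ± 8.68), SSY5, of amino acid sensing (388.4 nt ± 0.666), and ART5, of arrestin-related trafficking (388.1 nt ± 3.52). These values are limited by the end of the window at 400 nt, where RIP1 had its highest position, and 18 genes had their most used position beyond 390 nt. By construction, positions 1 to 300 give other values, 81.5 nt for HAC1 and 188.3 nt for ART5, and positions 21 to 400 give 70.1 nt for SEE1.

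Well-studied genes differed in how many sites they used. CYC1, of cytochrome c (YJR048W, chromosome X, 526335 to 526664, plus strand), put 95.9% ± 2.53 (SD, n = 2) of its reads on 1 position, 174 nt after the stop codon. ACT1, of actin (YFL039C, chromosome VI, 53260 to 54696, minus strand), spread over several sites. Its leading position took 13.3% ± 0.747 of the reads, was 98 nt in replicate 1 and 289 nt in replicate 2, and its mean endpoint was 164.8 nt ± 1.02. The glycolytic gene TDH3 ended at 101.0 nt ± 0.0570, PGK1 at 140.4 nt ± 0.301 and the alcohol dehydrogenase gene ADH1 at 81.0 nt ± 1.33. Among genes with a standard name, the highest shares at 1 position belonged to SSN2, of Mediator (96.8% ± 1.45 at 334 nt), RPL41A, of the ribosome (96.1% ± 0.148 at 210 nt), CYC1, RFA1, of replication protein A (93.4% ± 0.699 at 73 nt), and LIP2, of lipoylation (93.3% ± 0.561 at 106 nt). The effective number of positions, the exponential of the Shannon entropy of the profile, was highest for VMA1, of the vacuolar ATPase (38.4 ± 5.28, SD, n = 2), RAD14, of excision repair (33.8 ± 4.53), ACO1, of aconitase (32.4 ± 1.40), PTI1, of the cleavage machinery (31.0 ± 1.12), and DAD3, of the kinetochore (30.7 ± 2.26).

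Across all 4939 genes the leading position took a median of 33.5% ± 0.0794 (SD of the replicate medians, n = 2) of a gene's reads, and 947 genes (19.2%) put more than 50% of their reads there. The median effective number was 8.45 ± 0.0173 positions (SD of the replicate medians, n = 2). It exceeded 20 in 127 genes and lay under 2 in 26. The middle of each profile, from its 10th to its 90th percentile of reads, spanned a median of 44 nt and 45 nt.

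**Figure D2:**
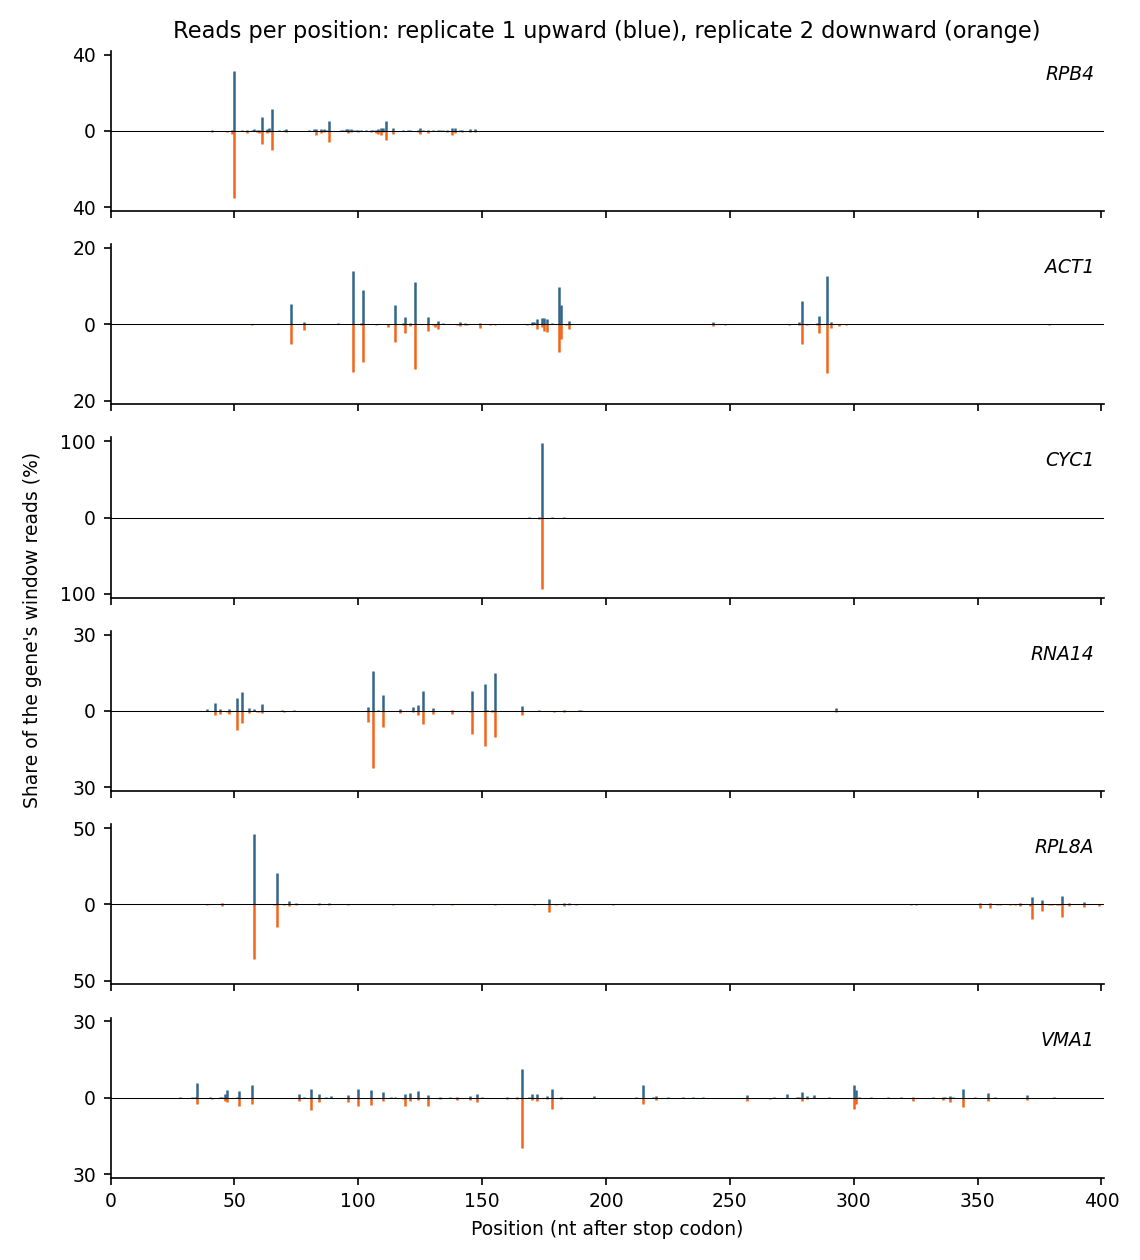
Share of each gene's window reads (percent, vertical axis, with a scale of its own per gene) at each position after the stop codon (nt) for RPB4, ACT1, CYC1, RNA14, RPL8A and VMA1, with replicate 1 upward in blue and replicate 2 downward in orange. CYC1 has 1 line, at 174 nt, and ACT1 and VMA1 have many.

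Reads inside the ORF were counted for RNA14 and CBP1, which are known for truncated transcripts, and for SUA7 and ACT1. Whether such reads mark poly(A) sites or priming on A-rich stretches was not tested. RNA14, of cleavage factor IA, had 35.1% (Wilson 95% interval 33.6 to 36.6) of its ORF and window reads inside the ORF in replicate 1 and 39.7% (38.1 to 41.2) in replicate 2. For CBP1, of cytochrome b mRNA stability, the shares were 40.2% (37.6 to 42.9) and 37.2% (34.7 to 39.8). SUA7, of transcription factor IIB, had 6.77% (4.47 to 10.1) and 7.18% (5.04 to 10.1), and ACT1 0.475% (0.301 to 0.750) and 0.850% (0.609 to 1.19). In the window after the stop codon, CBP1 had 79.9% ± 3.17 (SD, n = 2) of its reads at 93 nt, RNA14 ended at 116.0 nt ± 0.794 and SUA7 at 270.0 nt ± 3.57.

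The next comparison set 16 gene lists, fixed before the data were examined, against all other genes used. Oxidative phosphorylation genes had the longest 3' ends of these lists. Their median endpoint was 221.7 nt (replicates 222.4 and 212.6) against 122.4 nt for the other genes, a difference of 99.2 nt (100.3 and 89.4 nt in the replicates), and 32 of 37 members lay beyond the genome median. The permutation test gave an adjusted p of 0.00016 (two-sided, Benjamini-Hochberg over 16 lists, the smallest the permutations can give). RIP1 and SDH2, of succinate dehydrogenase (357.0 nt ± 1.73, SD, n = 2), were the longest members, and COX5B, of cytochrome c oxidase (77.6 nt ± 0.893), and ATP7, of ATP synthase (97.9 nt ± 0.247), were the shortest. RIP1 was the 1 member with its leading position in the last 10 nt of the window. The windows of COX5B and ATP7 overlap another feature on the same strand.

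Cytosolic ribosomal protein genes had short 3' ends. Their median was 99.6 nt against 123.6 nt, a difference of -24.0 nt (-23.5 and -23.6 nt in the replicates), with 44 of 137 members beyond the genome median and an adjusted permutation p of 0.00216. These genes were read deeply, with a median of 40836 window reads over both replicates. Against random lists matched on reads they lay at percentile 0.31, with a weaker unadjusted permutation p of 0.0092. Members ranged from RPL15B (52.2 nt ± 0.202, SD, n = 2) and RPS22B (53.7 nt ± 0.255), whose window overlaps another feature on the same strand, to RPL38 (259.4 nt ± 3.26) and RPS20 (289.1 nt ± 0.646). Cell wall protein genes had long 3' ends, with a median of 164.2 nt, a difference of 41.7 nt (40.4 and 42.5 nt in the replicates), 21 of 26 members beyond the genome median and an adjusted permutation p of 0.0309. Their longest members were PIR3 (345.9 nt ± 2.78, SD, n = 2) and the yapsin gene YPS1 (328.4 nt ± 0.193), and their shortest were CCW12 (60.7 nt ± 0.703) and TIR2 (74.3 nt). The cell wall call was lost with no filter on reads (difference 36.0 nt, adjusted permutation p = 0.0799) and without genes whose window overlaps a same-strand feature (33.6 nt, adjusted p = 0.172), and its adjusted p ran from 0.0108 to 0.172 over the alternatives.

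The other 13 lists did not pass the test. Histone genes all lay beyond the genome median (10 of 10), with a median of 166.6 nt and an adjusted permutation p of 0.155. They ran from HTB1 (124.5 nt ± 1.06, SD, n = 2) and HHT1 (142.0 nt ± 1.58) to HHT2 (247.2 nt ± 0.164) and the linker histone gene HHO1 (260.3 nt ± 15). Mating type and pheromone genes had a median of 149.9 nt (7 of 10 beyond, adjusted permutation p = 0.404), with BAR1 (79.8 nt ± 0.191), AGA1 (72.5 nt ± 1.45), STE2 (200.2 nt ± 0.591) and STE3 (261.3 nt ± 2.0) at the ends. RNA polymerase II subunit genes had a median of 127.0 nt (7 of 12, adjusted permutation p = 0.827), from RPB11 (55.0 nt ± 0.136) and RPB4, whose window reads are of unknown source, to RPB2 (263.1 nt ± 2.27) and RPB10 (296.7 nt ± 0.399). In positions 1 to 300 the value of RPB2 was 70.4 nt. Glycolysis and fermentation genes had a median of 126.2 nt (10 of 19, adjusted permutation p = 0.827), from ENO2 (52.7 nt ± 3.82) and FBA1 (54.6 nt ± 0.295) to PFK1 (211.1 nt ± 0.982) and PFK2 (264.5 nt ± 2.57). Of the genes named in this paragraph, AGA1 and ENO2 have windows that overlap another feature on the same strand.

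Amino acid synthesis genes had a median of 104.0 nt, with 22 of 64 members beyond the genome median (p = 0.0303 and adjusted permutation p = 0.121), and included TYR1 (56.3 nt ± 0.402), MET10 (57.1 nt ± 1.17), ARO3 (221.5 nt ± 3.63) and ILV5 (223.6 nt ± 6.29). Chaperone and heat shock genes had a median of 101.1 nt (8 of 25, adjusted permutation p = 0.323), from SSA3 (60.4 nt ± 0.976) to SSC1 (203.0 nt ± 4.67). Ergosterol synthesis genes had a median of 105.2 nt (9 of 24, adjusted permutation p = 0.404), and their longest members were ERG11 (270.3 nt ± 0.573) and ERG25 (296.8 nt ± 2.53, and 196.5 nt in positions 1 to 300). Proteasome genes had a median of 109.3 nt (11 of 32, adjusted permutation p = 0.465), from PRE7 (58.5 nt ± 1.17) to RPN13 (226.9 nt ± 1.07). Ribosome biogenesis genes had a median of 115.0 nt (31 of 70, adjusted permutation p = 0.547), from UTP10 (61.6 nt ± 0.0830) to IMP3 (342.4 nt ± 0.302). Mitochondrial ribosomal protein genes had a median of 116.4 nt (29 of 65, adjusted permutation p = 0.652), from RSM22 (52.4 nt ± 0.399) to MRPL39 (256.9 nt ± 4.66). Cleavage and polyadenylation factor genes also had a median of 116.4 nt (9 of 22, adjusted permutation p = 0.803), from CLP1 (55.9 nt ± 0.184) and YSH1 (63.0 nt ± 0.0957) to SYC1 (265.1 nt ± 0.170) and NPL3 (265.8 nt ± 4.81). Translation factor and tRNA synthetase genes had a median of 119.8 nt (21 of 43, adjusted permutation p = 0.827), from GUS1 (63.0 nt ± 0.0484) to NIP1 (274.5 nt ± 5.29). The 5 auxotrophic marker genes used had a median of 102.4 nt (2 of 5, adjusted permutation p = 0.654), from ADE2 (60.4 nt ± 0.208) to HIS3 (127.7 nt ± 4.60). Of the genes named in this paragraph, SSA3, CLP1, YSH1, GUS1 and HIS3 have windows that overlap another feature on the same strand.

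**Figure D3:**
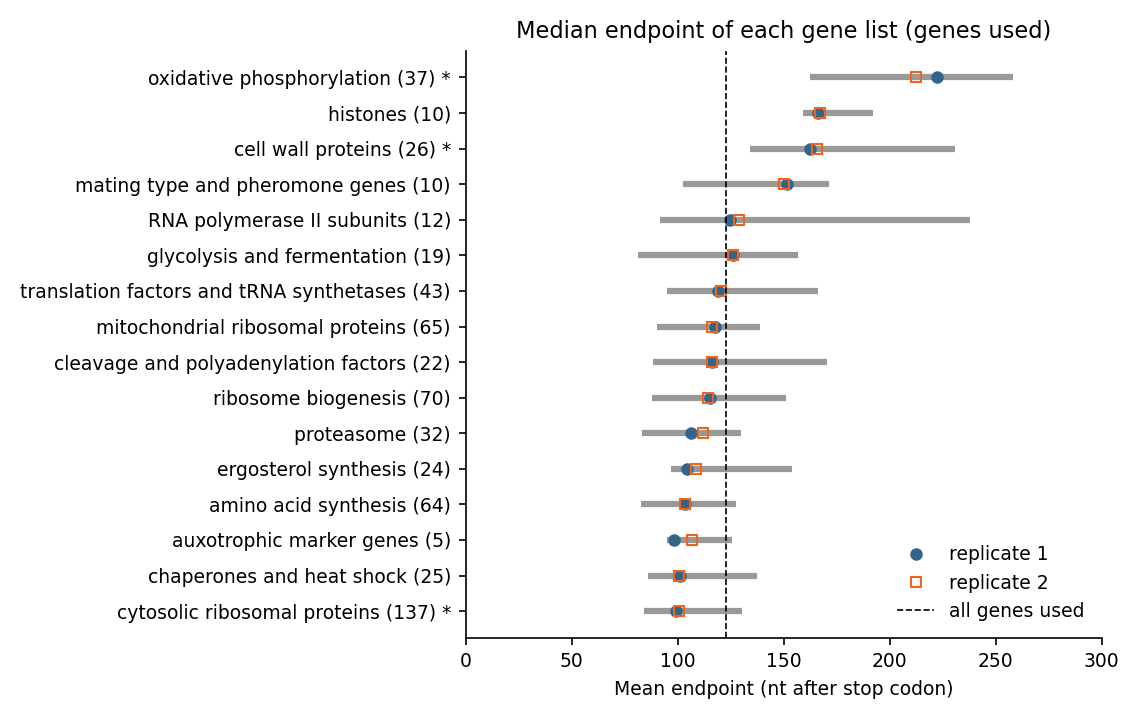
Median mean endpoint (nt after the stop codon) of each gene list in replicate 1 (filled circles) and replicate 2 (open squares), with the middle 50% of the members' values as grey bars, the number of genes used in brackets, the median of all genes used as a dashed line and an asterisk at adjusted p under 0.05. Oxidative phosphorylation lies furthest to the right, at 222.4 and 212.6 nt, and cytosolic ribosomal proteins lie at 99.2 and 100.6 nt.

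In the number of sites used, none of the 16 lists passed the same permutation test. Cell wall protein genes came closest, with a median of 11.1 effective positions against 8.44 (difference 2.62, with 2.60 and 3.01 in the replicates), 20 of 26 members above the genome median, permutation p = 0.0118 and adjusted p = 0.189. It was the 1 list with an unadjusted p under 0.05. Cytosolic ribosomal protein genes had 7.66 against 8.49 positions, with 55 of 137 members above the genome median (permutation p = 0.0698, adjusted p = 0.558). Against random lists matched on reads they lay at percentile 75.8 (unadjusted permutation p = 0.541), so their number was not low among genes read as deeply. The difference from all other genes stayed negative under the 12 alternatives run (-1.37 to -0.325). Cell wall genes lay at percentile 99.6 of their matched lists (unadjusted permutation p = 0.0037). Both lists passed under 1 alternative each, cell wall genes thinned to 100 reads (difference 2.64, adjusted permutation p = 0.0478) and cytosolic ribosomal proteins with positions under 1% set to 0 (-1.16, adjusted p = 0.0195).

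The paralogous pairs of ribosomal protein genes, which encode near-identical proteins, often ended at different distances. RPL6A ended at 72.0 nt ± 0.20 (SD, n = 2) and RPL6B at 243.1 nt ± 6.70. RPS0A ended at 65.2 nt ± 2.13 and RPS0B at 214.5 nt ± 0.730, and RPS1A at 199.0 nt ± 0.548 and RPS1B at 58.5 nt ± 0.388. RPL42A (88.2 nt ± 0.475) and RPL42B (88.6 nt ± 3.25) lay closest to each other, and RPL37A (93.0 nt ± 2.20) and RPL37B (93.8 nt ± 0.474) were next. These pairs were chosen after their values were seen, as the extremes of the 59 pairs. The median difference within a pair was 45.0 nt, with 26 pairs over 50 nt apart and 8 within 10 nt. Random pairings of the same genes had a median of 36.8 nt (95% of them from 27.1 to 48.2), so the pairs were not closer than random ones, nor past the threshold for lying further apart (two-sided permutation p = 0.121). How reads that match both copies were placed is not given in the sources used here.

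The last comparison asked how 3' ends related to the next annotated feature. Where the features did not overlap, 3' ends were shortest with the neighbour at less than 100 nt in convergent pairs and at 100 to 199 nt in tandem pairs. Among genes with a convergent neighbour (on the other strand, transcribed towards the gene), the median endpoint was 91.3 nt for 316 genes with less than 100 nt between the features and 165.0 nt for 192 genes with at least 500 nt. Among genes with a tandem neighbour (on the same strand) it was 94.2 nt for 146 genes at 100 to 199 nt and 146.5 nt for 547 genes at 500 nt or more. Across genes, endpoint and distance had a Spearman correlation of 0.329 in convergent and 0.275 in tandem pairs (adjusted permutation p = 1.5e-05 each, the smallest that can be reached, over 3 tests). In pairs whose features overlap, the endpoint was 130.3 nt for 177 convergent and 156.5 nt for 57 tandem genes, and it was 115.9 nt for 46 tandem genes with less than 100 nt.

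Over all distances, the 2633 genes with a convergent neighbour had a median endpoint of 125.1 nt and the 2069 with a tandem neighbour 120.9 nt, a difference of 4.18 nt (two-sided permutation test, adjusted p = 0.0171). That difference was not past the threshold with no filter on reads (3.44 nt, adjusted permutation p = 0.0809). It turned to -18.1 nt (adjusted p = 1.5e-05) without genes whose window overlaps a same-strand feature, a rule that by its construction takes out the tandem genes with close neighbours, and the tandem correlation then was 0.0331 (adjusted p = 0.295). At equal distance, convergent genes had the longer ends from 100 nt on, for example 138.7 nt against 96.7 nt at 200 to 299 nt. The differences within distance classes were not tested.

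**Figure D4:**
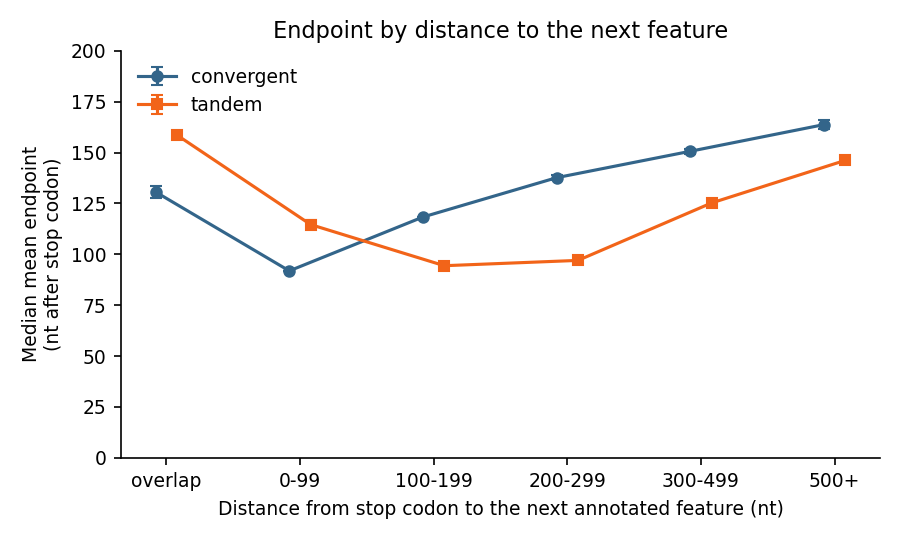
Mean over the replicates of the median mean endpoint (nt after the stop codon, vertical axis from 0) by the distance to the next annotated feature (nt) for genes with a convergent (blue circles) and a tandem neighbour (orange squares), with bars for the SD of 2 replicates. Convergent genes run from 91.9 nt at less than 100 nt to 163.7 nt at 500 nt or more.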

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

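The tests on snoRNA reads in this part were chosen after the read totals of the snoRNA windows had been seen. Features that are not ORFs, and the bodies of ORFs, are outside the measurement of 3' ends, and all of these held reads. The windows after 77 snoRNA genes, which encode guides of rRNA modification, held 40234 reads in replicate 1 and 24569 in replicate 2. Windows after 275 tRNA genes held 31995 and 28753 reads, and 174 of these windows, with 67.8% of the reads, share no position with another same-strand feature or its window. The bodies of ORFs held 580386 and 539771 reads.

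The snoRNA with the most reads was SNR72 (3534 and 2735 reads), and its leading position was 42 nt after the annotated end in both replicates, but its window shares positions with another same-strand feature or its window, so these reads may not be its own. SNR40 had 2146 and 304 reads, led by the first position after its end, and SNR9 had 1660 and 940. Of 45 snoRNAs with at least 100 reads in both replicates, 41 lay below the median ratio of replicate 2 to replicate 1 of all genes. After scaling to the library totals their median log2 ratio was -0.44, against 0.09 for all genes, and 0.0001 of random lists matched on reads lay as far out, the smallest share 10000 draws can give. Only 22 of the 45 have windows that share no position with another same-strand feature or its window. Others of the 45 may share reads, so the count of 41 and the share of 0.0001 do not rest on independent members. A difference in sequencing depth would leave the median near that of all genes, so it does not account for the shortfall in replicate 2.

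Reads of a neighbouring gene on the same strand could be the source of part of the snoRNA signal. Windows that share no position with another same-strand feature or its window held 38.7% of the snoRNA reads, which lies between the bounds set for that explanation, so for snoRNA windows as a whole the sources cannot be told apart. Within such separate windows, 22 snoRNAs still had at least 100 reads in both replicates, which argues against annotated neighbours as their source, and their median log2 ratio was -0.70. Whether the shortfall came from the cultures, from RNA isolation or from library preparation was not tested. The replicates have 1 strain and 1 condition, so no biological explanation was tested either.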

How the results depend on the processing

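No paired analysis was possible because the samples form 1 group. The comparison of sequence around the most used position was not run, since no genome was used here, and leaving out a replicate gives no value for the agreement of replicates. All feature types, verified ORFs and thinning to 100 reads were chosen after seeing the data. The calls for oxidative phosphorylation (differences from 71.2 to 107.1 nt, adjusted p from 0.00016 to 0.0016) and for cytosolic ribosomal proteins (from -26.6 to -19.0 nt, adjusted p from 0.00096 to 0.0491) held under all 13 alternatives run. The distance correlation of convergent genes held under 5 (0.319 to 0.333), and the paralog test stayed short of its threshold under 9. Endpoints of named genes were counted only where positions are left out, since filters leave a profile as it is and a replicate alone always lies within 1 SD of the mean of 2. Of 285 such values, 93 moved by 1 SD or more (32 in positions 1 to 300, 13 in positions 21 to 400 and 48 with positions under 1% set to 0), and 12 moved by more than 1.5 times. In positions 1 to 300 these were SSN2 (103.1 nt), HAC1 (81.5 nt), ERG25 (196.5 nt), ART5 (188.3 nt), PTI1 (124.2 nt), TIF4631 (130.6 nt), RPL8A (74.4 nt), MPP10 (76.1 nt), MCM1 (112.7 nt) and RPB2 (70.4 nt), and in positions 21 to 400 SEE1 (70.1 nt) and DIP2 (94.6 nt). The lists that changed direction below were all short of the threshold before and after. Unless a reason is given, the cause was not tested.

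Leaving out a replicate, the share at the leading position was 33.5% to 33.6% and the effective number 8.43 to 8.46. In the pooled table the share was 33.4%, the number 8.96 and the amino acid synthesis difference in number -0.274. With no filter on reads, the profile correlation was 0.977, genes with the same leading position 78.3%, its share 34.7%, the endpoint 124.9 nt and the number 7.97. The cell wall endpoint difference was then 36.0 nt (adjusted permutation p = 0.0799), convergent minus tandem 3.44 nt (adjusted p = 0.0809), and the differences in number 0.536 for chaperones, 0.259 for ribosome biogenesis and 0.0590 for translation factors.

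With at least 1000 reads, the correlation was 0.991, the same leading position 89.4%, its share 34.7%, the endpoint 119.2 nt and the number 8.54. The endpoint difference of cleavage factors was 6.36 nt, and differences in number were 0.847 for RNA polymerase II, 0.308 for chaperones and 0.0214 for ribosome biogenesis. In positions 1 to 300, which by construction drop distal reads, the share was 34.4%, the endpoint 119.7 nt and the number 8.06, with endpoint differences of -10.8 nt for RNA polymerase II and 0.0615 nt for translation factors and a difference in number of 0.102 for chaperones. In positions 21 to 400 the share was 33.9% and the number 8.39. With positions under 1% set to 0, which by construction removes minor sites, the share was 35.6%, the endpoint 121.8 nt and the number 6.73. The difference in number passed the threshold for cytosolic ribosomal proteins (-1.16, adjusted permutation p = 0.0195, with 0.0195 to 0.919 over the alternatives), and was -0.156 for oxidative phosphorylation, -0.352 for the proteasome, -0.162 for amino acid synthesis and -0.00369 for auxotrophic markers.

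Without overlapping windows, the correlation was 0.980, the share 33.4%, the endpoint 129.6 nt and the number 8.64. Endpoint differences were 33.6 nt for the cell wall (adjusted permutation p = 0.172), -3.41 nt for glycolysis, -2.62 nt for RNA polymerase II, 2.66 nt for cleavage factors and 4.21 nt for ergosterol, and the difference in number was 0.0521 for ribosome biogenesis. Convergent minus tandem was -18.1 nt (adjusted p = 1.5e-05) and the tandem correlation 0.0331 (adjusted p = 0.295), since the rule removes close tandem neighbours by construction. With all feature types the share was 33.5% and the number 8.51. Thinned to 100 reads, the correlation was 0.945, the same leading position 76.5%, its share 34.5% and the number 7.64, and the cell wall difference in number passed the threshold (2.64, adjusted p = 0.0478, with 0.0478 to 0.571 over the alternatives).

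Spearman's coefficient gave a median of 0.697, and 5-nt bins gave 0.986. The median position gave an endpoint of 118.0 nt, and the most used position 117.0 nt. The highest 5-nt sliding sum was at the same place in 74.3% of genes. The inverse Simpson number was 5.33, and the better-read part of the genes had an effective number of 8.49. By median position, endpoint differences were -3.50 nt for RNA polymerase II, 8.5 nt for cleavage factors and 3.0 nt for translation factors, and by most used position -3.50, 13.5 and 7.0 nt. By the inverse Simpson number, differences were -0.0401 for cleavage factors, 0.0123 for chaperones, -0.235 for oxidative phosphorylation, -0.00885 for the proteasome and -0.122 for auxotrophic markers.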

Other observations

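In this part, the test of read depth on oxidative phosphorylation genes was chosen after their median had been seen, and the genes named below were picked by their values. Some genes had nearly all of their reads inside the ORF and few after the stop codon. Among 3689 ORFs into which no same-strand neighbour or its window reaches, 478 had more than 10% of their reads inside the ORF in both replicates and 82 had more than 50%, while the median was 1.04% and 1.01%. TAF2, of transcription factor IID, had 287 and 291 reads inside the ORF and 0 in the window. MET3, of sulfate assimilation, had 98.8% ± 0.681 (SD, n = 2) of its reads inside the ORF, on 1731 and 1093 such reads. CTF19, of the kinetochore, had 98.7% ± 1.8, CLG1 98.2% ± 0.698 and RPM2, of mitochondrial RNase P, 96.2% ± 4.30. Whether these reads mark poly(A) sites or priming on genomic A-rich stretches was not tested, since no genome sequence was used here.

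Read counts of 2 pairs of genes of related function, picked by their values, lay far apart. HHT2, of histone H3, had 15374 ± 1781 window reads per 1000000 ORF window reads (SD, n = 2), and HHT1, which encodes the same protein, 308.1 ± 23.4. Among glycolytic genes, ENO2 had 12696 ± 3077 and PGK1 125.8 ± 5.06. PDC1, of pyruvate decarboxylase, had 15887 ± 5075 on the same scale, more than HHT2 in replicate 1 and less in replicate 2. These are counts of reads without molecular identifiers, and how reads that match both copies of a duplicated gene were placed is not given in the sources used here.

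The long 3' ends of oxidative phosphorylation genes were weighed against 3 technical explanations. Read depth would let random lists matched on reads reach the same median, and a share of 0.0001 did, the smallest 10000 draws can give. Reads of an annotated downstream gene could lie only in overlapping windows, which 5 of the 37 members have. Without overlapping windows the difference was 97.3 nt, but leaving out so few members could hardly have shrunk it. A few distal reads would leave the most used position in place, but it differed by 89.0 nt. The values argue against all 3, the second by the count of overlapping windows and for annotated features only. A candidate explanation is that long 3' ends are a property of these genes in this strain, which is a hypothesis found and tested on the same data. Distance to the next feature and priming on A-rich stretches were not tested for this list. Whether the parental strain shares the long ends was not tested either.

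Replicate 1 had more reads than replicate 2 for several genes of oxidative and xenobiotic responses. GRE2, a reductase gene, was 4.49-fold higher in replicate 1 after scaling to library totals (2336 and 473 reads), AAD16 3.46-fold, GTT2, a glutathione transferase gene, 3.17-fold and SRX1, of sulfiredoxin, 3.06-fold. In replicate 2, SNO1 was 5.39-fold, CHA1, of serine catabolism, 3.58-fold and FET4, a metal transporter gene, 2.43-fold higher. Only 52 genes differed by more than 2-fold between the replicates.

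That pattern was tested on a list of 27 other genes of such responses, written before their ratios were seen, of which 23 were used. Their median log2 ratio of replicate 2 to replicate 1 was -0.22, against 0.09 for all genes, and 20 of 23 lay below the latter. Sampling noise would place it among random lists matched on reads (95% of them from -0.05 to 0.20), and a share of 0.0002 of these lay as far out. A difference in depth moves all genes of a library alike, so it cannot open a gap between the list and all genes, with or without the scaling to library totals. The test compares 2 libraries, so the hypothesis that the first culture was in a mild stress response and a difference in library preparation may each account for it, and no biological explanation was tested.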
